A study of Mus musculus with 16 samples.

How the data were processed

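T cell receptor (TCR) sequences were read from single CD4+ T cells of mouse spleen. Per the labels' protocols, mice received an antibody that depletes cells bearing NK1.1 (50 µg, days -2 and 5), an intravenous graft of Vk12653 multiple myeloma cells at day 0, and an agonistic antibody against the costimulatory receptor 4-1BB (also called CD137) or control IgG (20 µg, days 10, 13 and 16). CD44high CD4+ T cells, the antigen-experienced fraction, were sorted from spleen at day 18. Eomes wild-type (WT) and Eomes knockout (KO) mice were compared, which gives 4 groups of 2 libraries, 1 from each of 2 experiments that the labels mark as batches. Per the labels, the KO of experiment 1 used a Cre expressed under the CD4 promoter and the KO of experiment 2 a tamoxifen-dependent Cre, with tamoxifen also given to the WT mice of experiment 2, so the type of knockout and the experiment cannot be told apart. The 8 TCR libraries were analysed; the 8 gene expression libraries made from the same samples were not analysed here.

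Each deposited file lists the assembled TCR contigs of 1 library with their V, D and J labels, the amino acids and nucleotides of the third complementarity-determining region (CDR3), and, per the file headers, the count of reads and of unique molecular identifiers (UMIs) behind each contig. Per the submitters' processing notes, the tools were Cell Ranger 7.1.0, bcl2fastq 2.20.0 and Seurat, with the genome build GRCm38. The V(D)J reference was not given in the sources used here. Tested on the files, 0 of the 123611 contigs were marked as outside cells, as low confidence, as incomplete or as not productive, and 0 carried a chain other than TRA or TRB. A cell whose second chain was removed before deposit therefore looks like a cell that never had it. Of the 166 V and J labels in the files, 165 matched a gene symbol of the GRCm38.p6 annotation. The remaining label joins TRBV12-2 and TRBV13-2, and 99.7% of its contigs carried the CDR1 of TRBV13-2, so it was read as TRBV13-2 and kept as its own label in the tests.

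Depth ranged from 80551 to 445027 TCR UMIs and from 8039901 to 15045635 reads per library. The median contig rested on 10 to 17 UMIs for TRB and 6 to 10 for TRA. Both medians were higher with anti-4-1BB than with IgG in every combination of experiment and genotype, so treatment and UMI depth moved together. For TRB they went from 11 to 17 (WT) and 10 to 13 (KO) in experiment 1. In experiment 2 the TRB medians went from 11 to 15 and 12 to 15. Confidence intervals of shares are 95% binomial intervals (Clopper-Pearson, or Wilson where named) and cover counting error alone.

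Cells with 1 TRB and 1 or 2 TRA chains were kept, 38108 of 74368. Cells with 2 TRB chains were left out as possible doublets. A clonotype was a set of cells of 1 library with the same TRB and the same main TRA (V and J segments and CDR3 nucleotides). The expanded share is the percent of cells in clonotypes of 2 or more cells, as the exact expected value after thinning each library to 2656 cells, the number in the smallest library. The Simpson concentration is the probability that 2 cells drawn from a library share a clonotype and was compared on the log2 scale. The invariant natural killer T (NKT) TCR share is the percent of cells with TRAV11 or TRAV11D joined to TRAJ18.

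These values were compared with two-sided exact permutation tests that exchange treatment labels inside the 4 combinations of experiment and genotype, or genotype labels inside the 4 combinations of experiment and treatment. The 16 arrangements cannot give a p below 0.125, so no such result can pass 0.05. Labels exchanged inside experiments (36 arrangements) cannot go below 0.0556, and exchanged over the 8 libraries (70 arrangements) not below 0.0286. Comparisons of 2 against 2 libraries (6 splits) cannot go below 0.333 and are given as values. Over the 24 stratified tests the lowest Benjamini-Hochberg adjusted p of the exact permutation tests was 0.75. The difference between expanded and single clonotypes was tested over the 256 sign patterns of 8 libraries.

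Segment use was tested with edgeR 4.0.16 in R 4.3.3, a quasi-likelihood test on the number of clonotypes per segment, each clonotype counted once. There was 1 fit for each of the 4 segment types with 4 group means, and the total of the segment type as library size. In the TRAV fit the prior degrees of freedom were infinite. The SE and p of each TRAV segment therefore rest on a spread pooled over all TRAV segments, not on its own. Segments needed 10 or more clonotypes in at least 2 libraries, which kept 153. Benjamini-Hochberg adjusted p-values over all of them were called under 0.05. DESeq2 1.42.0, trimmed mean (TMM) factors, an abundance trend (loess), no filter, cells in place of clonotypes, a minimum of 3 UMIs per chain, the experiment as a term and leaving out each library were tried as alternatives. Other values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and the figures drawn with matplotlib 3.10.9.

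The labels name each experiment as a batch, so libraries of the same experiment are paired. The sources used here do not say how many mice stand behind a library, so p-values measure the spread between these libraries alone. Deviations from the group means, over the 153 segments, correlated between same-experiment libraries with r from -0.138 to 0.458 in the 6 pairs of groups. The experiment as a term (the replicate block) moved the segments called in the KO comparison of treatments from 1 to 2.

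The text names each segment called (up to 20 per comparison). Where fewer than 10 were called it also names the 5 with the smallest p in each direction, as values that did not pass. The Vβ8 and Vβ5 families, TRAV11, TRAV11D, TRAJ18, TRAV1 and TRAJ33 are always named, as are the largest clonotype of each library and the TRB chains found in 6 or more libraries. Lists fixed beforehand were the Vβ8 family (TRBV13-1, TRBV13-2, TRBV13-3), the Vβ5 family (TRBV12-1, TRBV12-2), the usual β partners of invariant NKT cells, Vβ families with a single gene, the TRBJ1 and TRBJ2 clusters, and TRAJ segments numbered above 30 or not. Marker receptors of other cells were invariant NKT, mucosal-associated invariant T (TRAV1 with TRAJ33), γδ T cell and immunoglobulin chains. These choices, tests and lists were made before the data were examined, and alternatives added later are named as such. The joined label was put into the Vβ8 and β partner lists once it was seen in the files.

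The segment test was tested on simulated counts for anti-4-1BB against control IgG, with 20 segments changed in each of 10 simulations. It recovered 28.0% of segments changed 1.5-fold, 77.6% of those changed 2-fold, 98.0% at 3-fold and 100% at 4-fold. The simulated counts had 1 common spread per segment type, no difference between experiments and the same change in both genotypes. In the data some treatment values moved apart between the experiments, so recovery there may be lower. Changed segments were drawn among those under 2% of their type, and 17 of the 167 calls (10.2%) were of unchanged segments. In a first simulation that also changed common segments this share was 20.8% (40 of 192 calls), since a large change in a common segment moves the shares of the others; the rarer segments were chosen after that was seen. Simulations without any change gave 0 calls. The thinning formula lay within 0.113 percentage points of the mean of 200 random draws.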

Results

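The TCR repertoire was measured in CD44high CD4+ T cells from the spleen of myeloma-bearing mice, to ask how agonistic anti-4-1BB treatment and loss of the transcription factor Eomes change the clones among these cells. There were 8 libraries, 2 for each of WT with control IgG, WT with anti-4-1BB, Eomes KO with control IgG and Eomes KO with anti-4-1BB, with 1 library of each group from each of 2 experiments. The files held 4637 to 14657 cells per library. Cells with a TRB chain and no TRA chain made up 25.9% to 46.8% of a library. Paired receptors came from 4057, 8871, 2728 and 2656 cells in experiment 1 (WT IgG, WT anti-4-1BB, KO IgG, KO anti-4-1BB) and from 4459, 4439, 5991 and 4907 cells in experiment 2, so the smallest libraries limit what rare receptors can be seen.

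With anti-4-1BB, clones took a smaller part of the cells than with control IgG in experiment 1 and a larger part in experiment 2, in WT and in KO alike. In experiment 1 the expanded share was 19.3% in WT with IgG and 11.9% with anti-4-1BB, and 22.5% and 16.5% in KO. In experiment 2 it was 21.3% and 41.4% in WT and 21.1% and 30.99% in KO. The IgG libraries of all 4 combinations lay between 19.3% and 22.5%, so the spread was among the anti-4-1BB libraries. Over both genotypes the difference was 4.12 ± 13.2 points (SD, n = 4 strata, 2 of 4 higher; exact permutation test, p = 0.625). Within experiment 1 it was -6.72 ± 1.07 points and within experiment 2 14.97 ± 7.19 points (SD, n = 2 genotypes), each larger than the spread between genotypes, and no permutation test of 2 values can pass 0.05. Without thinning, the treatment difference in WT in experiment 1 was -0.716 points in place of -7.48.

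**Figure D1:**
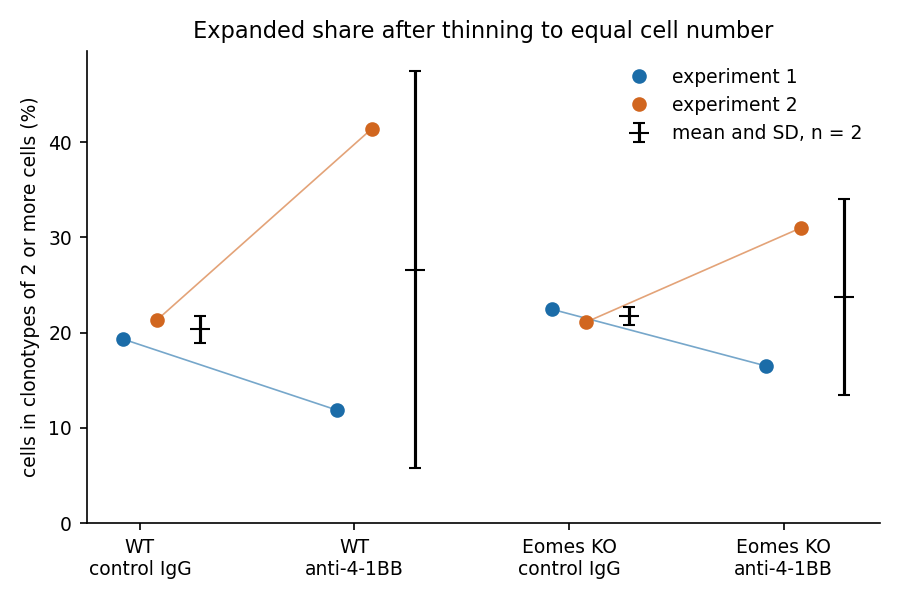
Percent of cells in clonotypes of 2 or more cells (vertical axis, after thinning to equal cell number) in the 4 groups; points are libraries, thin lines join the treatments of an experiment, black bars are mean and SD of 2 libraries. The WT libraries with anti-4-1BB sit at 11.9% in experiment 1 and 41.4% in experiment 2, and the IgG libraries between 19.3% and 22.5%.

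The concentration of the repertoire went the same way. In WT, 1 pair of cells in 4226 shared a clonotype with IgG and 1 in 11904 with anti-4-1BB in experiment 1, against 1 in 4094 and 1 in 709 in experiment 2. In KO the corresponding pairs were 1 in 3034 and 1 in 8296, and then 1 in 3917 and 1 in 1041. On the log2 scale anti-4-1BB minus IgG was 0.37 ± 2.15 (SD, n = 4 strata; exact permutation test, p = 0.75), made of -1.47 in experiment 1 and 2.22 in experiment 2. The 10 largest clonotypes held 9.46% of the cells in WT and 7.56% in KO with anti-4-1BB in experiment 2, and between 1.97% and 4.30% in the 6 other libraries.

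With libraries thinned to equal cell number, the difference in clonal expansion between KO and WT over both treatments was smaller than the spread between strata. The expanded share in KO minus WT was -0.714 ± 6.76 points (SD, n = 4 strata, 2 of 4 higher; exact permutation test, p = 0.875), with 3.88 points in experiment 1 and -5.31 in experiment 2. Without thinning it was -3.43 points, with -2.97 in experiment 1 and -3.89 in experiment 2. Unthinned values also rise with cell number, and with anti-4-1BB in experiment 1 WT had 8871 and KO 2656 paired cells. The log2 Simpson concentration differed by 0.13 ± 0.50 (SD, n = 4 strata; exact permutation test, p = 0.75). Within IgG the expanded share in KO minus WT was 1.45 ± 2.37 points and within anti-4-1BB -2.88 ± 10.6 points (SD, n = 2 experiments). The treatment difference was 6.29 ± 19.5 points in WT and 1.96 ± 11.2 in KO, and their difference was -4.33 ± 8.26 points (SD, n = 2 experiments; exact permutation test with 4 arrangements, p = 1, smallest possible 0.5). Without thinning, KO minus WT within anti-4-1BB was -7.94 ± 3.14 points (-5.72 in experiment 1, -10.2 in experiment 2) and the difference of treatment effects -9.01 ± 4.99 points (SD, n = 2 experiments; exact permutation test, p = 0.5, the smallest possible).

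Cells with the receptor of invariant NKT cells, which recognise lipids on CD1d and often carry NK1.1, were scarcer with anti-4-1BB in every combination of genotype and experiment. Their share in experiment 1 was 0.271% with IgG and 0.101% with anti-4-1BB in WT, and 0.587% and 0.339% in KO. In experiment 2 it was 1.37% (61 of 4459 cells, interval 1.05% to 1.75%) against 0.158% (7 of 4439, 0.0634% to 0.325%) in WT, and 1.75% (105 of 5991, 1.44% to 2.12%) against 0.265% (13 of 4907, 0.141% to 0.453%) in KO. Anti-4-1BB minus IgG was -0.779 ± 0.669 points (SD, lower in 4 of 4 strata; exact permutation test, p = 0.125, the smallest that 16 arrangements allow). It was -0.209 points in experiment 1 and -1.35 in experiment 2, and in experiment 1 the intervals of the treatments overlapped (WT 0.135% to 0.485% and 0.0464% to 0.193%; KO 0.336% to 0.951% and 0.155% to 0.642%).

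**Figure D2:**
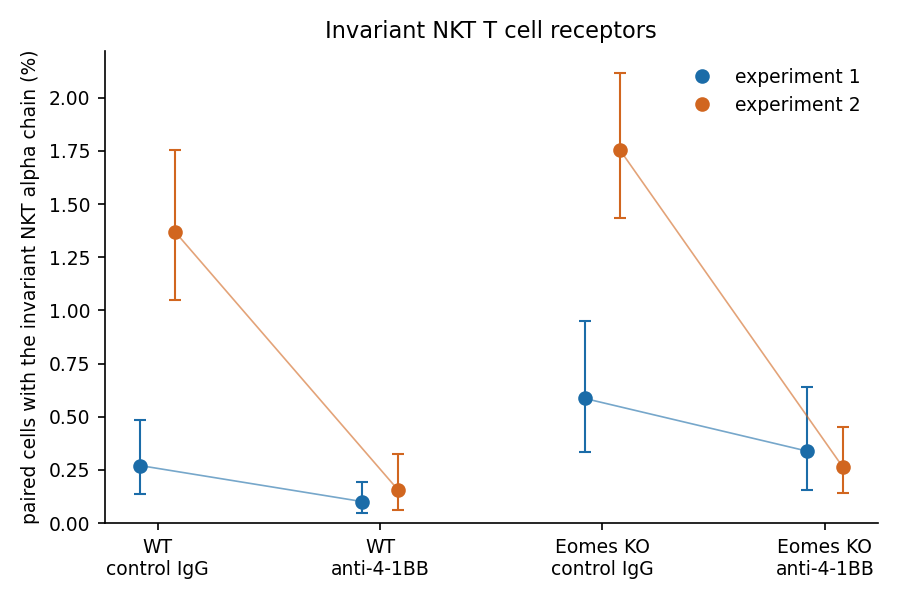
Percent of paired cells with the invariant NKT alpha chain (vertical axis) in the 4 groups; points are libraries, bars their 95% Clopper-Pearson intervals, and lines join the treatments of an experiment. The IgG libraries of experiment 2 stand at 1.37% and 1.75%, and every anti-4-1BB library at 0.339% or below.

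The same cells were more frequent in KO than in WT in 4 of 4 strata, by 0.261 ± 0.119 points (SD, n = 4, exact permutation test, p = 0.125, the smallest possible). The exact permutation p was 0.389 with labels exchanged inside experiments and 0.486 with labels exchanged over the 8 libraries. The intervals of WT and KO overlapped in 4 of 4 strata. The difference was 0.350 ± 0.0490 points within IgG and 0.172 ± 0.0920 within anti-4-1BB (SD, n = 2 experiments). Among all 231 such cells, 47.2% used the joined TRBV13-2 label, against 12.2% of other cells, and 19.5% used TRBV29, against 1.84%, both known partners of the invariant alpha chain. Of the other listed partners, TRBV13-3 had 10.8% against 6.46% and TRBV13-2 1.73% against 1.49%. Lower than in other cells were TRBV13-1 (4.33% against 6.40%) and TRBV1 (4.33% against 7.18%). Receptors of mucosal-associated invariant T cells were seen in 0 to 2 cells per library, while the deposited files list TRA and TRB chains alone, so the 0 γδ T cell and 0 immunoglobulin chains in them say nothing about such cells.

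Counted by clonotypes, the TRA segments of that receptor were used less with anti-4-1BB. TRAV11 (chromosome 14, 53519303 to 53519859, GRCm38) fell by 1.56 on the log2 scale (-1.56 ± 0.30 SE, edgeR adjusted p = 5.07e-05), from 1.05% and 1.598% of clonotypes with IgG in WT and KO to 0.387% and 0.575% with anti-4-1BB. It was lower in 4 of 4 strata. Its SE and p rest on the spread pooled over the TRAV segments. TRAJ18 (chromosome 14, 54200777 to 54200842) also fell (-0.65 ± 0.17 SE, edgeR adjusted p = 0.0380), from 2.79% and 3.65% to 1.86% and 2.26%, and again in 4 of 4 strata. These were the 2 calls among 153 segments, where 5 had an unadjusted p under 0.05. DESeq2 called 0 (5 at unadjusted p under 0.05), counting cells called 0 (5 at unadjusted p under 0.05), and the calls went to 0 when the WT anti-4-1BB library of experiment 1 or the WT IgG, WT anti-4-1BB or KO IgG library of experiment 2 was left out. TRAV11 stayed between -0.83 and -1.91 over all 8 libraries left out in turn, and 1 call was left without the KO IgG library of experiment 1 or the KO anti-4-1BB library of experiment 2.

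No segment was called higher with anti-4-1BB. The 5 with the smallest p were TRBJ2-4 (log2 0.23 ± 0.07 SE), TRBV3 (0.26 ± 0.13), TRBV12-1 (1.77 ± 0.90), TRAJ33 (0.26 ± 0.16) and TRAV6D-4 (0.54 ± 0.35). Among those lower, TRBV29 (-0.36 ± 0.11), TRBV14 (-0.41 ± 0.16) and TRBJ1-2 (-0.17 ± 0.08) followed the 2 called segments. None of these 8 passed (edgeR adjusted p from 0.273 to 0.959).

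**Figure D3:**
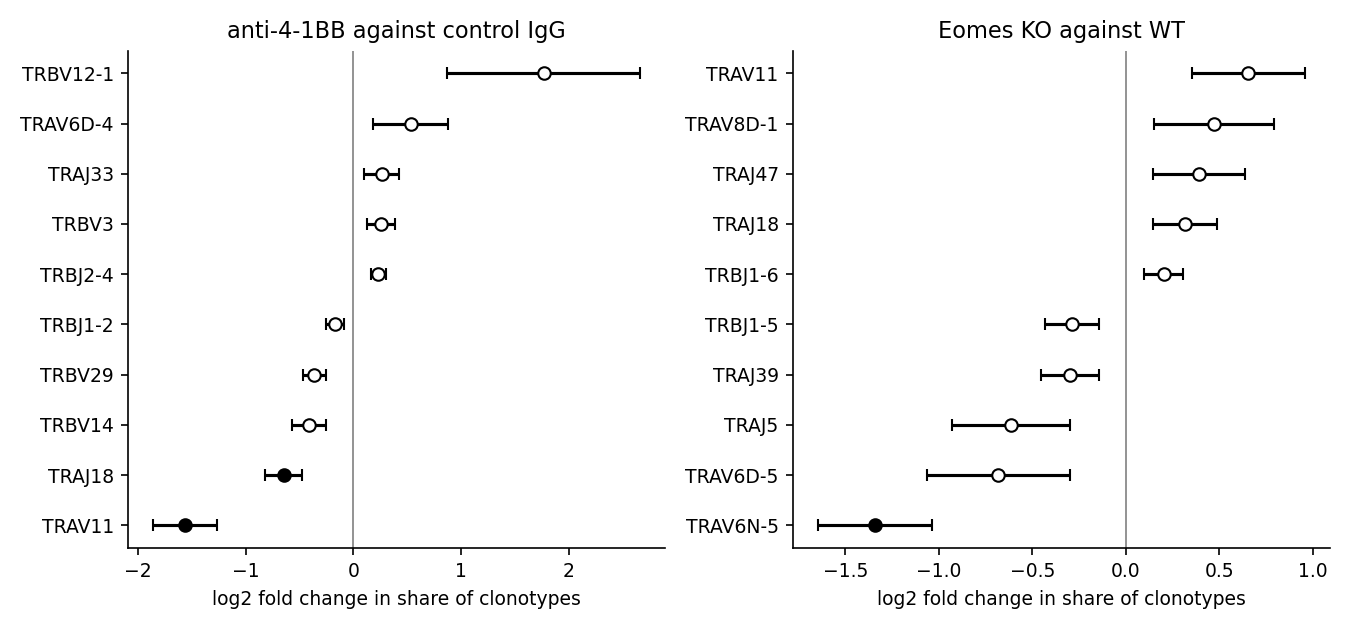
Log2 fold change of the share of clonotypes (horizontal axis, bars are standard errors from edgeR, n = 8 libraries) for the segments named for anti-4-1BB against IgG (left) and KO against WT (right); filled points were called. TRAV11 at -1.56, TRAJ18 at -0.65 and TRAV6N-5 at -1.34 are the called segments.

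The large standard error of TRBV12-1 came from opposite values in the experiments. TRBV12-1 (chromosome 6, 41113567 to 41114067) encodes a chain of the Vβ5 family. Its share of clonotypes in experiment 1 was 1.84% with IgG and 6.63% with anti-4-1BB in WT, and 0.910% and 8.36% in KO. In experiment 2 it was 1.15% and 0.924% in WT and 1.05% and 0.650% in KO. TRBV12-2, the other Vβ5 gene, stood at 1.58% and 2.32% (WT) and 0.694% and 4.51% (KO) in experiment 1. A fit over all 8 libraries, added after seeing the data, had a mean for each combination of experiment and treatment. The genotypes served as its replicates, and both experiments shared the estimate of the spread. In this fit TRBV12-1 rose in experiment 1 (log2 2.38 ± 0.29 SE, edgeR adjusted p = 0.00531) and had -0.49 ± 0.36 in experiment 2.

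The treatment difference in experiment 2 minus that in experiment 1 was -2.87 ± 0.46 (edgeR adjusted p = 0.0376), and 0 segments were called in that contrast with genotype as a term (28 at unadjusted p under 0.05; DESeq2 without that term called 1). Leaving out any library of experiment 2 ended the call of TRBV12-1 in experiment 1 (2.38 to 2.39 on the log2 scale) as well as that of the difference (-2.62 to -3.12). TRAV11 and TRAJ18 were called in experiment 2 (-2.03 ± 0.31 and -1.07 ± 0.19) and not in experiment 1 (-0.68 ± 0.40 and -0.22 ± 0.20), and for neither did the difference between experiments pass (edgeR adjusted p = 0.207 and 0.192).

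**Figure D4:**
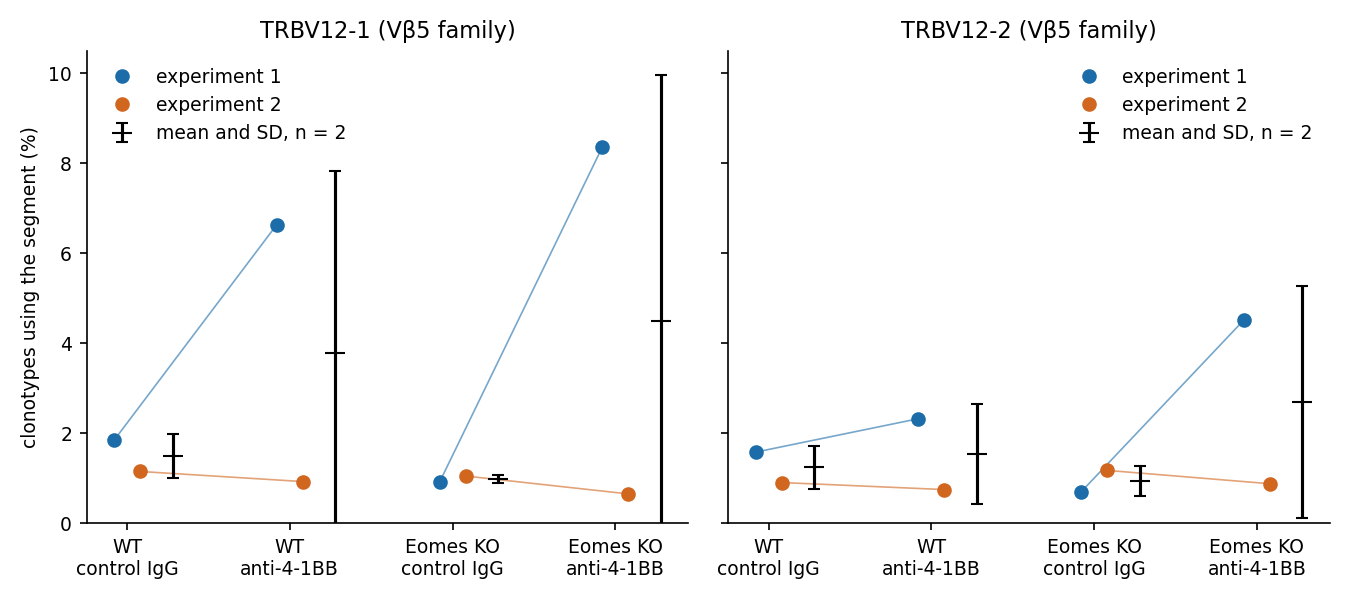
Percent of clonotypes using TRBV12-1 (left) and TRBV12-2 (right) in the 4 groups; points are libraries, lines join the treatments of an experiment, black bars are mean and SD of 2 libraries and end at the axis where they would pass below 0. For TRBV12-1 the anti-4-1BB libraries of experiment 1 stand at 6.63% and 8.36%, and the 6 others at 1.84% or below.

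Within WT, 0 segments were called for the treatment by edgeR (5 at unadjusted p under 0.05; DESeq2 0). TRAV11 had -1.57 ± 0.43 (edgeR adjusted p = 0.0507), and 1 segment was called without the WT IgG or KO anti-4-1BB library of experiment 1 or the KO anti-4-1BB library of experiment 2. The other segments with the smallest p were TRBJ1-1 (0.33), TRBV19 (0.67), TRAV7N-4 (1.40), TRAJ53 (0.45) and TRAJ16 (0.43) on the higher side, and TRAJ18 (-0.56), TRBV14 (-0.51), TRBJ2-1 (-0.16) and TRBV17 (-0.92) on the lower. Within KO, TRAV11 fell (-1.56 ± 0.42, edgeR adjusted p = 0.0315) as the 1 call. With the experiments as a replicate block 2 were called, TRAV11 and TRAJ18; 0 were called with TMM factors, an abundance trend or DESeq2 (6, 4 and 4 at unadjusted p under 0.05), or without either WT anti-4-1BB library, either KO anti-4-1BB library or the KO IgG library of experiment 2. Values that did not pass within KO were TRBJ2-4 (0.31), TRAJ26 (0.41), TRAJ30 (0.41), TRAV13-1 (0.56) and TRAJ33 (0.39), and TRAJ18 (-0.74), TRBV29 (-0.49), TRAV5N-4 (-0.81) and TRAJ52 (-0.47). The difference of the treatment effects between genotypes gave 0 calls with edgeR (5 at unadjusted p under 0.05; DESeq2 0). Its smallest p-values were of TRAV6N-5 (1.25), TRAV13N-1 (0.98), TRAJ24 (0.75), TRAJ26 (0.49) and TRAJ35 (0.81), and of TRAJ5 (-1.46), TRBJ1-1 (-0.40), TRBV19 (-1.04), TRAV9-1 (-1.63) and TRAV7N-4 (-1.73).

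Eomes KO differed from WT in 1 segment. TRAV6N-5 (chromosome 14, 53104871 to 53105344) fell by 1.34 on the log2 scale (-1.34 ± 0.31 SE, edgeR adjusted p = 0.00258; 2 segments at unadjusted p under 0.05), and was lower in KO in 4 of 4 strata. The widest gap was in experiment 1 with IgG, 2.10% in WT against 0.303% in KO, and the other shares lay between 0.377% and 1.15%. Without the WT IgG library of experiment 1 TRAV6N-5 had -0.81 and 0 were called. The call also ended without the WT anti-4-1BB library of experiment 1 (-1.07) or experiment 2 (-1.49) or the KO anti-4-1BB library of experiment 2 (-1.14), while 2 were called without the WT IgG library of experiment 2 (TRAV6N-5 and 1 higher); DESeq2 and cells counted gave 0 (1 each at unadjusted p under 0.05). TRAV6N-5 is one copy of a duplicated segment family, and its label depends on telling near-identical copies apart.

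Values that did not pass for KO against WT (edgeR adjusted p = 0.996 each) were TRAV11 (0.66 ± 0.30), TRAJ18 (0.32 ± 0.17), TRBJ1-6 (0.20 ± 0.11), TRAJ47 (0.39 ± 0.24) and TRAV8D-1 (0.47 ± 0.32) on the higher side. TRAJ5 (-0.61 ± 0.31), TRAJ39 (-0.30 ± 0.16), TRBJ1-5 (-0.29 ± 0.14) and TRAV6D-5 (-0.68 ± 0.38) were on the lower. With IgG alone TRAV6N-5 was again the 1 call (-1.96 ± 0.44, edgeR adjusted p = 0.00190; without WT IgG of experiment 1 it had -0.91, and the call also ended without either WT anti-4-1BB library or either KO IgG library, at -1.86 to -2.17). Other values with IgG were TRBJ1-6 (0.32), TRAV5N-4 (0.78), TRAV11 (0.65), TRAJ18 (0.40) and TRAV9-1 (0.93), and TRAV13N-1 (-0.74), TRAJ24 (-0.56), TRBJ2-1 (-0.14) and TRAV6D-5 (-0.82). Of these, TRAV11 had -0.05 without the WT IgG library of experiment 1 and -0.15 without the KO IgG library of experiment 2, and it was called at 2.13 without the WT IgG library of experiment 2. With anti-4-1BB alone 0 were called by edgeR (1 at unadjusted p under 0.05; DESeq2 0). The smallest p-values there were of TRAV8D-1 (0.74), TRAV13D-1 (0.70), TRAV11 (0.66), TRAJ35 (0.50) and TRAJ26 (0.28), and of TRAJ5 (-1.35), TRAV8D-2 (-0.87), TRBJ1-5 (-0.39), TRBV19 (-0.53) and TRAV6N-5 (-0.72).

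The shares of the Vβ8 and Vβ5 families, lists fixed beforehand, lay further apart between treatments in experiment 1 than in experiment 2. This contrast between experiments was not tested for the lists. Vβ8 made up 29.6% and 23.6% of WT clonotypes (IgG, anti-4-1BB) and 30.3% and 25.9% of KO clonotypes in experiment 1, and between 27.6% and 28.7% in experiment 2. Its treatment difference was -2.34 ± 3.37 points, that of Vβ5 3.93 ± 5.67 points (8.40 in experiment 1, -0.538 in experiment 2), each SD over n = 4 strata (exact permutation test, p = 0.5 for both). Of the 4 Vβ8 labels and the 2 Vβ5 genes, 0 were called by edgeR over all 153 segments and 0 adjusted over the list alone. TRBV13-1 had -0.18 ± 0.18, TRBV13-2 -0.42 ± 0.28, the joined label TRBV12-2+TRBV13-2 -0.03 ± 0.12, TRBV13-3 -0.14 ± 0.18 and TRBV12-2 0.91 ± 0.61 for the treatment. For KO against WT they had -0.05 ± 0.18, 0.00 ± 0.29, 0.10 ± 0.12, -0.04 ± 0.18 and 0.18 ± 0.61, and TRBV12-1 -0.20 ± 0.88. TRAV1 had -0.28 ± 0.32 for the treatment and -0.27 ± 0.32 for the genotype, TRAJ33 -0.02 ± 0.16 for the genotype, and no clonotype used TRAV11D.

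The β partners of invariant NKT cells differed by -3.66 ± 4.07 points with treatment (exact permutation test, p = 0.25; 0 of 6 members called), Vβ families with a single gene by -1.53 ± 2.35 (p = 0.375; 0 of 14), the TRBJ1 cluster by -0.661 ± 2.45 (p = 0.625; 0 of 6) and TRAJ segments above 30 by -0.00628 ± 2.10 (p = 1; 0 of 22), each SD over n = 4 strata. For genotype the same lists gave 0.840 ± 1.40 (exact permutation test, p = 0.375), -1.74 ± 3.30 (p = 0.5), 0.440 ± 1.83 (p = 0.75) and -0.0687 ± 2.999 points (p = 0.875), Vβ8 0.396 ± 1.38 (p = 0.75) and Vβ5 0.531 ± 2.42 (p = 0.75), with 0 members called by edgeR. Adjusted over the list alone, the treatment call in the TRBJ2 cluster was 1 of 6 (TRBJ2-4) and that in TRAJ segments of 30 or below 1 of 21 (TRAJ18). Over all segments these were 0 and 1.

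Clonotypes of 2 or more cells and clonotypes of 1 cell, compared inside each library, differed in 2 labels. TRAV11 made up 0.230% of expanded and 0.982% of single clonotypes (mean of 8 libraries) and was lower among expanded ones in 8 of 8 libraries (-2.31 ± 0.46 SE, edgeR adjusted p = 0.00318). The label TRBV13-2 made up 0.573% and 2.05% (-1.67 ± 0.29, edgeR adjusted p = 0.00205), also lower in 8 of 8. Of the 520 single TRBV13-2 clonotypes, 100 had the same CDR3 nucleotides and alpha chain under the joined label in the same library. With the joined label counted as TRBV13-2, an alternative added after seeing the data, the segment had -0.07 and the call ended, so the 1 remaining call was TRAV11. Without the KO IgG library of experiment 2 the call of TRAV11 ended (-2.12). Of the 231 invariant NKT receptor cells, the WT anti-4-1BB library of experiment 1 and the KO IgG library of experiment 2 each held 1 expanded clonotype and the 6 other libraries 0.

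Further values of that comparison were TRAJ12 (0.43 ± 0.16), TRAV13N-1 (0.55 ± 0.22), TRBV10 (0.30 ± 0.12), TRAV6-2 (0.68 ± 0.29) and TRAV4-2 (0.66 ± 0.30) among segments higher in expanded clonotypes. TRBV12-1 (-0.85 ± 0.27), TRAV10N (-0.84 ± 0.29) and TRAJ18 (-0.54 ± 0.21) were among those lower, and none passed (edgeR adjusted p from 0.218 to 0.408). In the Vβ5 family 1 of 2 genes, TRBV12-1, was called adjusted over the list alone, and 0 over all segments; TRBV12-1 was lower among expanded clonotypes in 4 of 8 libraries and higher in the other 4. The CDR3β was as long in expanded as in single clonotypes within the spread between libraries, with a difference of 0.00965 ± 0.107 amino acids (SD, n = 8, higher in 6 of 8; exact permutation test, p = 0.797). It was 0.1599 in WT and -0.203 in KO with anti-4-1BB in experiment 2, and the mean was -0.0216 with clonotypes weighted by cells and -0.0118 without the former library. Mean hydropathy differed by -0.00684 ± 0.0378 (SD, n = 8; exact permutation test, p = 0.617).

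With anti-4-1BB the CDR3β was shorter than with IgG in 4 of 4 strata, by a mean of -0.0677 ± 0.0162 amino acids (SD; exact permutation test, p = 0.125, and 0.0556 with labels exchanged inside experiments, each the smallest possible). Its hydropathy was higher in 4 of 4, by 0.0244 ± 0.0315 (SD, n = 4; exact permutation test, p = 0.125), made of 0.0207 in WT and 0.0700 in KO in experiment 1 and 0.00599 and 0.00103 in experiment 2. KO minus WT was -0.00690 ± 0.0299 amino acids and -0.00508 ± 0.0205 in hydropathy (SD, n = 4; exact permutation test, p = 0.75 for both).

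TRB chains were mostly private to a library. Of 27235 distinct chains (TRBV, CDR3 amino acids, TRBJ), 26215 were found in 1 library and 6 in 6 or more. TRBV20 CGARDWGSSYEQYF was found in all 8, in 30 cells with 27 different alpha chains. TRBV1 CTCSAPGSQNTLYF (7 libraries, 20 cells) was joined in 18 cells to the alpha chain TRAV13-1 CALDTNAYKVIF, and TRBV1 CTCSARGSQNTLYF (6 libraries, 40 cells) in 29 cells to the same chain. All 11 cells with TRBV5 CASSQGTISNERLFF (7 libraries) used TRAJ22. TRBV20 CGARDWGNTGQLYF (8 cells) and TRBV3 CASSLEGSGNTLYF (6 cells), each in 6 libraries, had a different alpha chain in every cell. Between experiments, the number of shared chains per 1000000 pairs of clonotypes was 4.58 with the same treatment and 4.11 with different treatments, a difference of 0.471 (exact permutation test over 36 arrangements, p = 0.222). Without the KO IgG library of experiment 2 the difference was 0.273 and without the KO anti-4-1BB library of experiment 2 0.794. The number was 4.54 with the same genotype and 4.15 with different genotypes, a difference of 0.392 (exact permutation test, p = 0.444), which was 0.0404 without the KO IgG and 0.641 without the KO anti-4-1BB library of experiment 1.

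The largest clonotypes were bigger with anti-4-1BB in experiment 2 than elsewhere. In KO the largest there was TRBV20 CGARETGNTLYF with TRAV14-2 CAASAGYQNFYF, 1.45% of cells (interval 1.13% to 1.82%), and in WT TRBV13-1 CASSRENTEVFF with TRAV14N-1 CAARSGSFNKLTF, 1.37% (1.05% to 1.76%). With IgG in experiment 2 they were TRBV20 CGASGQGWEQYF with TRAV3N-3 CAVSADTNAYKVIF in WT (0.695%, 0.473% to 0.985%) and TRBV10 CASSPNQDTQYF with TRAV4-4-DV10 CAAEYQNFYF in KO (0.551%, 0.379% to 0.773%). In experiment 1, TRBV15 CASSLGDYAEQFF with TRAV14-2 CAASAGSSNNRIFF led WT with IgG (0.739%, 0.499% to 1.05%) and TRBV12-2 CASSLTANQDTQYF with TRAV14D-3-DV8 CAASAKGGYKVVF led KO with IgG (0.733%, 0.448% to 1.13%). With anti-4-1BB in experiment 1, TRBV13-1 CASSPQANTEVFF with TRAV7D-2 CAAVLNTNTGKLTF held 0.225% in WT (0.138% to 0.348%) and TRBV10 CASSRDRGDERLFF with TRAV7D-2 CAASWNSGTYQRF held 0.414% in KO (0.207% to 0.740%).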

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

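Several tests were chosen after the results were seen. They were on large TRBV12-1 clonotypes, low expansion of TRBV12-1 cells, all cells of 1 TRB, removal of Vβ5 cells and TRAV11 counted by clonotype. TRA UMIs against other cells, the contrast of each experiment in the shared fit and other splits of the libraries were also chosen then. The tests on CDR1, the 10 largest clonotypes and TRA UMIs of invariant NKT receptor cells were written down before.

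Vβ5 use moved apart between the experiments: the treatment difference of TRBV12-1 in experiment 2 minus experiment 1 was -2.87 on the log2 scale, called by edgeR (adjusted p = 0.0376) but not with genotype as a term or without any library of experiment 2 (-2.62 to -3.12), and that of the Vβ5 list -8.94 points, untested. The largest TRBV12-1 clonotype held at most 1.44% of the TRBV12-1 cells in the anti-4-1BB libraries of experiment 1. Each clonotype was counted once, so a few large clones could not raise the share of clonotypes, and this value decides nothing about it. Of the TRBV12-1 contigs of these libraries 100% carried the common TRBV12-1 CDR1. This argues only weakly against shared V labels, since V labels are themselves read from the sequence. TRBV12-1 cells were less expanded than cells without Vβ5, by -10.4 points in KO and -17.4 in WT, which may point to many added cells that had divided little; the gap was -17.0 and -39.4 points in experiment 2 (26 and 27 cells), where TRBV12-1 was not more common, and between -3.09 and 5.01 points in the 4 IgG libraries, so it was seen with anti-4-1BB in both experiments and is not special to the rise. Whether these cells had another identity than the sorted CD44high CD4+ cells was not tested, since the expression libraries were not analysed here. A biological difference between the experiments, such as tamoxifen, stays open and untested; the knockout allele cannot account for the values in WT.

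Clonal expansion with anti-4-1BB had opposite signs in the experiments, in both genotypes and untested as a difference: experiment 2 minus experiment 1 was 21.7 points for the expanded share, 3.69 for the log2 Simpson concentration and 6.92 points for the 10 largest clonotypes. Uneven recovery of alpha chains has against it that all cells with 1 TRB gave 19.2 points, with the signs kept in both genotypes. That value used TRB nucleotides alone and another cell number for thinning. Cells without TRA moved the same way with anti-4-1BB, in experiment 1 from 42.3% to 25.9% (WT) and 33.8% to 30.9% (KO). In experiment 2 they went from 42.0% to 46.6% and 36.4% to 46.8%. A part in the size stays open, as KO in experiment 2 had 6.13 points against 9.88 with paired cells. Without Vβ5 cells the difference in experiment 1 was -4.73 ± 2.15 points (SD, n = 2), so these cells could account for at most a part of it. Without the 10 largest clonotypes the difference in experiment 2 was 12.4 points, so it did not rest on them alone. Differences between experiments in mice, tamoxifen or tumour growth stay open and were not tested.

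Invariant NKT receptors were scarcer with anti-4-1BB in 4 of 4 strata. Growth of a few other clones has against it that TRAV11 had -1.56 ± 0.30 with each clonotype counted once. That count differs from the share of cells, as 46.5% of WT and 36.3% of KO cells with anti-4-1BB in experiment 2 were in expanded clonotypes (unthinned). In experiment 1 the expanded share was lower with anti-4-1BB. Growth spread over many other clones would lower both counts. It stays open, as 84.4% to 92.7% of the clonotypes of a library were single cells. So does a weaker recovery of their alpha chain: the median TRA UMI number of these cells was equal or higher with anti-4-1BB in 4 of 4 strata, but it counts recovered chains alone, and its ratio to that of other cells was lower in 4 of 4. An effect of the antibody on these cells is a hypothesis that remains open, as does a different efficiency of NK1.1 depletion between cages, which may act on the same cells and has no measurement here; the IgG libraries of experiment 2 had more TRAV11 clonotypes than those of experiment 1 (log2 1.68 ± 0.31, edgeR adjusted p = 1.59e-05), but not past the test without the WT IgG library of experiment 1 (1.07), and DESeq2 and cells counted called 0 segments there (8 and 14 at unadjusted p under 0.05).

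Chance cannot be excluded for the number of segments called by treatment or genotype. The treatment called 2 segments and the highest other split of 4 against 4 libraries called 3, with 6 of 35 splits calling at least as many. Many of the 35 splits, among them that with 3 calls, were unbalanced between the experiments. A balanced split also called 2, with both WT libraries of experiment 1 and both anti-4-1BB libraries of experiment 2 on one side. The genotype called 1 and the highest other split 3, with 11 of 35 calling at least as many. Parting the libraries by experiment called 0. For expanded against single clonotypes, 2 were called in the real arrangement and at most 1 in the others, so 1 of 100 arrangements gave as many, but this rests on the label TRBV13-2. With the joined label counted as TRBV13-2, 1 was called in the real arrangement and at most 1 in the others, 9 of 100 gave as many, and chance cannot be excluded.

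Other effects also had opposite signs in the experiments, in every pair of libraries and without a test of the difference. For KO minus WT these were the expanded share (-9.19 points in experiment 2 minus experiment 1), the CDR3β length (-0.0513 amino acids), the Vβ8 list (-2.08 points) and TRAJ segments above 30 (-4.72 points). For anti-4-1BB minus IgG they were the Vβ8 list (5.71 points) and TRAJ segments above 30 (-2.91 points). The Vβ8 value is not independent of the Vβ5 rise in experiment 1, since both are shares of the same clonotypes. Without thinning, KO minus WT in expanded share was -2.97 points in experiment 1 and -3.89 in experiment 2. The unthinned share also rises with cell number, and with anti-4-1BB in experiment 1 WT had 8871 and KO 2656 paired cells. The log2 Simpson concentration needs no thinning. Its KO minus WT was 0.499 in experiment 1 and -0.245 in experiment 2, though not opposite in every pair of libraries. Of 24 comparisons between experiments 10 were opposite, where independent random signs would give 3. Several of them were measures of the same property, so this excess was not tested.

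Among cells left out of the comparisons, those with 2 TRB chains made up 9.33% of the WT anti-4-1BB library of experiment 1 (interval 8.86% to 9.81%), against 3.15% to 5.45% in the 7 others. That library also held the most cells, 14657.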

How the results depend on the processing

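Tests on all cells with 1 TRB, without Vβ5 cells or clonotypes, without invariant NKT receptors in the segment tests, with the joined label counted as TRBV13-2 and without the anti-4-1BB libraries of experiment 1 were chosen after the results were seen; the other settings were fixed before. The cause of each change below was not tested, unless said. Of 226 values that answer a comparison, recomputed under settings other than a library left out, 200 kept direction and side of the threshold, 22 moved and 4 reversed; of 807 for single named segments 779 kept both, 20 lost and 3 gained a call and 5 reversed. With a library left out, 119 of 160 and 598 of 632 kept both. Exact tests with labels exchanged inside strata or experiments could not pass 0.05 under any setting, so their side of it says little of stability. With labels exchanged over the 8 libraries in the main setting, the lowest exact permutation p of the 24 treatment and genotype tests was 0.0571. The no-filter setting for expanded against single clonotypes could not be fitted and was not run.

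For the treatment over both genotypes, 2 segments were called. With cells counted, with DESeq2 or without invariant NKT receptors, 0 were called (5, 5 and 2 at unadjusted p under 0.05). Removing these receptors takes out a part of the TRAV11 and TRAJ18 clonotypes, and left TRAJ18 at -0.18. Without the anti-4-1BB libraries of experiment 1, TRAV11 had -1.44 and TRAJ18 -0.84. With 3 or more UMIs per chain or without Vβ5 clonotypes, 1 was called. For KO against WT (1 called), 0 were called with cells counted, DESeq2 or without the anti-4-1BB libraries of experiment 1 (1, 1 and 2 at unadjusted p under 0.05). For the treatment in WT (0 called by edgeR, 5 at unadjusted p under 0.05, DESeq2 0), 1 was called without Vβ5 clonotypes and with the joined label. For the treatment in KO (1 called), the replicate block of the paired experiments gave 2, and TMM factors, DESeq2, cells counted, an abundance trend, removal of invariant NKT receptors and of the anti-4-1BB libraries of experiment 1 gave 0 (6, 4, 5, 4, 3 and 7 at unadjusted p under 0.05). The block changed no other count. For KO against WT with IgG (1 called), cells counted and DESeq2 gave 0 (2 and 1 at unadjusted p under 0.05). For expanded against single clonotypes (2 called), the joined label gave 1.

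With all cells of 1 TRB, KO minus WT was 0.798 points in expanded share and -0.10 in log2 Simpson concentration, both reversed, and 3.83 points in expanded share with IgG. Without the anti-4-1BB libraries of experiment 1, KO minus WT in log2 Simpson concentration was -0.00412, TRBV12-1 had -0.65 for the treatment, TRBJ1-5 0.0179 for the genotype and 0.22 for the genotype with anti-4-1BB, where TRAV11 had -0.0503 and TRAJ26 -0.0189. The CDR3β length, expanded minus single, was -0.0216 weighted by cells.

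With a library left out in turn, the treatment difference in expanded share ranged from -1.19 to 7.99 points, negative without either WT library of experiment 2, and KO minus WT from -2.50 to 2.51, positive without either anti-4-1BB library of experiment 2. The difference of treatment effects between genotypes ranged from -10.2 to 1.52 points, positive without any library of experiment 2. The log2 Simpson concentration ranged from -0.34 to 1.00 for treatment and -0.00412 to 0.35 for genotype, and the CDR3β length from -0.0118 to 0.0400. Segments called ranged from 0 to 2 for treatment, genotype and genotype with IgG, from 0 to 1 for treatment in WT and in KO, and from 1 to 2 for expanded against single. TRAJ30 in KO ranged from -0.0217 to 0.70, TRAV11 with IgG from -0.15 to 2.13 and TRBJ1-5 with anti-4-1BB from -0.59 to 0.18. A lone library in these fits is assumed to vary like the other groups. Depth limits rare receptors: 7 to 105 invariant NKT receptor cells stand behind each share.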

Other observations

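The definition of near-identical receptors and the tests of groups of them were chosen after seeing the data; the predictions on re-paired chains and on beta nucleotides were written before their results.

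Some receptors recurred as whole alpha-beta pairs in different mice. Pairs were called near-identical when clonotypes of different libraries shared TRBV, TRBJ and TRAJ, differed by at most 1 amino acid in each CDR3 and had different beta nucleotides, invariant NKT receptors left out. Of 30254 clonotypes 992 had such a partner, in 283 groups, 55 of them in 3 or more libraries. The group of TRBV1-TRBJ2-4 with TRAV13-1 or its copies and TRAJ30 was found in all 8 libraries, as 115 clonotypes and 510 cells. It held 32 forms of the CDR3β, led by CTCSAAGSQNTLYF (35 clonotypes), and 9 of the CDR3α, led by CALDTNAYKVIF (55 clonotypes).

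In experiment 2 this TRBV1 group made up 3.20% of cells with anti-4-1BB in WT (142 cells, Wilson interval 2.72% to 3.76%) and 6.50% in KO (319 cells, 5.84% to 7.23%), against 0.224% and 0.334% with IgG. In experiment 1 it was 0.123% and 0.0902% in WT and 0.0733% and 0.151% in KO (IgG, anti-4-1BB). Over both experiments anti-4-1BB minus IgG was 2.30 ± 2.93 points (SD, higher in 3 of 4 strata; exact permutation test, p = 0.25). The cells were spread over 24 clonotypes in WT and 49 in KO, the largest of 23 and 68 cells. Without the group the treatment difference in expanded share in experiment 2 was 12.5 points, against 14.97 with it. By genotype it was 18.7 against 20.1 points in WT and 6.34 against 9.88 in KO.

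Another group, TRBV5 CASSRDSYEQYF with TRAV13N-2 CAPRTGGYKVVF, held 97 cells in 44 clonotypes, 86 of these cells in WT with anti-4-1BB in experiment 1. The other anti-4-1BB libraries held 2 (KO, experiment 1), 1 (WT, experiment 2) and 8 cells (KO, experiment 2), and the IgG libraries 0. A group of TRBV26 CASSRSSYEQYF with TRAV13-1 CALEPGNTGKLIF held 66 cells, 40 of them in KO with anti-4-1BB in experiment 2. These TRBV5 and TRBV26 groups were picked from the data, as was the TRBV1 group, and neither was tested alone.

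Recurrent clonotypes were expanded more often than all clonotypes, by 15.5 ± 7.26 points (SD, higher in 8 of 8 libraries, exact permutation test, p = 0.00781, the smallest possible). A clonotype was recurrent only through a partner in another library, so the libraries are not independent, as the test assumes. The TRBV1 group was kept in this test, and all clonotypes included the recurrent ones. The recurrent share of a library's clonotypes differed by -0.172 ± 0.679 points for anti-4-1BB minus IgG (SD, higher in 1 of 4 strata, exact permutation test, p = 0.625). For KO minus WT it was 0.744 ± 0.857 points (SD, higher in 4 of 4, exact permutation test, p = 0.125). Between experiments, libraries of the same treatment had 8.51 near-identical pairs per 1000000 and those of different treatment 4.22, a difference of 4.29 (exact permutation test over 36 arrangements, p = 0.111). The mean was 13.0 between anti-4-1BB libraries and 4.05 between IgG libraries, so only the former lay above 4.22; without the TRBV1 group these were 3.38 and 3.18, against 1.38 with different treatments. Without that group the difference was 1.904 (exact permutation test, p = 0.111). For genotype the difference was 0.444 with the group (exact permutation test, p = 0.556) and -0.180 without it.

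Common chains meeting by chance are argued against by re-pairing alpha and beta chains inside each library, which gave a mean of 44.2 and at most 68 clonotypes with a partner in 100 re-pairings, against 992. Carry-over between libraries with read errors is argued against by nucleotides, as 65.7% of these clonotypes had a partner that differed at 3 or more CDR3β bases. Pairs with identical beta nucleotides were left out beforehand, so this does not test carry-over without errors. Of 30449 paired nucleotide clonotypes, 33 were found in more than 1 library, mostly in libraries of the same experiment. In the 28 pairs of libraries, 0 contigs shared both barcode and CDR3 nucleotides. Selection by shared antigens, of the tumour, the host or its microbes, is a hypothesis that may account for the near-identical pairs. No antigen was measured, so these sources were not tested.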
